A study of Mus musculus with 24 samples.

How the data were processed

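Gene expression was measured by RNA-seq in 24 libraries of transplanted mouse mammary tumours, in 6 groups of 4. The tumours came from MMTV-Wnt1 mice, in which a mouse mammary tumour virus promoter drives the growth factor gene Wnt1 in the mammary gland. Per the labels' protocols, RNA was purified on silica columns (RNeasy), and strand-specific libraries were built from 1 µg of total RNA with a SureSelect kit. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.36, STAR 2.5.0c and RSEM 1.2.31 were used with the mouse genome build mm10 (GRCm38). The annotation release, the parameters and whether the counting used the strand are not given in the sources used here. Named genes that overlap a gene with a mean of 1 TPM or more on the opposite strand are therefore given as uncertain.

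The authors deposited 1 table of TPM values (relative transcript abundances corrected for length) for 47729 genes, with 2 decimals and 1 column per library. Each column summed to 1000000. TPM divides by gene length and by the library total, so the table keeps no read depth. The depth of each library is therefore unknown, and no counting intervals or detection limits are given. TPM values are also relative: a rise of abundant genes lowers the values of all others. Gene identifiers were matched to the GENCODE M21 annotation of GRCm38, in which 47224 of the 47729 were found, and coordinates are taken from it.

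Values were transformed to log2(TPM + 1), and genes at 1 TPM or more in at least 4 libraries were kept, which left 15736 genes. Fold changes are on this log2(TPM + 1) scale, which understates the changes of genes with low values. Group means of the 6 groups were fitted to all 24 libraries together with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, 18 residual degrees of freedom), and contrasts gave the comparisons. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Unless stated otherwise, an adjusted p of a gene in the text is from this fit. The labels do not say that the 4 libraries of a group come from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

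There were 30 gene lists of pathways and of cell types that a mammary tumour can hold. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists within a comparison. The same test with the correlation estimated from the data, and limma's fry test, were run as alternatives. Fry asks whether the genes of a list move on balance in 1 direction (directional) or in either (mixed), without comparing them with other genes. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

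The groups, the fit, the lists, the rule for named genes and most alternatives were fixed before the data were examined. For each comparison of 50 mg/kg with vehicle, the rule took the 8 largest rises and the 8 largest falls among genes that passed, reached a mean of 5 TPM in 1 of the groups and did not overlap between the groups. Predicted genes, pseudogenes and receptor or immunoglobulin segments were left out. Up to 4 genes in each direction were taken for the other comparisons, where the differences between days did not need the non-overlap. Each list added up to 4 members that passed, or up to 2 with the smallest p where none did, and 10 genes were always named. Some genes that the rule takes are not reported here. Other list members in the text were chosen after their values were seen.

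Alternatives were TMM scaling factors, quantile normalization, no filter, a filter at 5 TPM, pseudocounts of 0.1 and 5, a fit of the compared groups alone, library weights, robust variances, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. After the data were seen, 4 were added: rescaling of the protein-coding genes, removal of each library's trend with transcript length, and the mean log2 level of the skeletal muscle or of the macrophage list as a covariate. An exact permutation test of the mean list level per library, over the 70 splits of 8 libraries, was added then too, as was leaving out each library for every list, the later ones included. So were the sizes of the calls that ended without the length trend and the list of vessel tip genes without 2 members.

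The steps were tested on simulated data for the comparison of 50 mg/kg with vehicle on day 4 over 15736 genes. Of the genes given a 1.5-fold change, 53.7% were called, against 83.6% at 2-fold and 95.5% at 4-fold, and 9 unchanged genes were called. A list of 20 genes shifted by 0.5 was found by camera with an adjusted p of 1.3e-22, while none of the other lists was called. The simulated genes varied independently and the lists were drawn at random. The simulation therefore cannot show how often camera at the preset correlation calls lists whose genes move together. No columns were identical, and the root mean square log2 difference between libraries of a group ranged from 0.334 to 0.616. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.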

Results

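Pieces of spontaneous MMTV-Wnt1 mammary tumours were grown in C57BL/6J mice to about 200 mm3, which was designated day 1. The mice then received vehicle or E7386, a compound known as a modulator of the interaction of β-catenin with its coactivator CBP, by mouth at 25 or 50 mg/kg 2 times daily. Tumours were collected after 3 days of dosing (day 4) or 7 days (day 8), with 4 libraries in each of the 6 groups. Between 14496 and 15127 genes reached 1 TPM per library. Mitochondrially encoded genes took 8.29% to 11.3% of the TPM total, and mt-Atp8 had the highest mean. The skeletal muscle gene Acta1 ranged from 0.21 to 290 TPM, with high and low libraries in every group except 25 mg/kg on day 4, where all 4 lay above 20 TPM.

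After 3 days at 50 mg/kg, 13 of 19 genes of the integrated stress response rose, and 18 of 19 cholesterol synthesis, 10 of 19 hypoxia and 15 of 32 proliferation genes fell. Asparagine synthetase, Asns, rose from 25.5 ± 2.66 to 166 ± 22.4 TPM (SD, n = 4; log2 fold change 2.66, SE 0.16, adjusted p = 2.0e-09). Idi1, whose enzyme makes a building block of cholesterol, fell from 59.0 ± 12.1 to 17.0 ± 3.40 TPM (-1.73, SE 0.25, adjusted p = 0.000143). The comparison asks what the higher dose changed early. By limma, 1457 of 15736 genes passed, 779 higher and 678 lower, and 110 of these changed at least 2-fold.

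Of the 19 measured genes of the integrated stress response, the programme that cells run when translation initiation is restrained, 13 rose and 1 fell (15 and 1 when adjusted over the list alone), with a median log2 fold change of 1.02. The list's adjusted p was 1.7e-14, and 0.0504 with an estimated correlation. Besides Asns, the cystine transporter gene Slc7a11 rose from 1.18 ± 0.53 to 11.0 ± 3.95 TPM, the stress-induced gene Nupr1 from 135 ± 31.6 to 554 ± 61.3 TPM, and Chac1, whose enzyme degrades glutathione, from 0.87 ± 0.16 to 12.5 ± 10.6 TPM (SD, n = 4 each). The transcription factor gene Ddit3 (1.18), the pseudokinase gene Trib3 (2.02), the serine synthesis genes Psat1 (1.02) and Phgdh (1.05) and the mitochondrial folate genes Shmt2 (1.02), Mthfd2 (2.05) and Aldh1l2 (1.84) rose as well, given as log2 fold changes. Atf4, which encodes the central transcription factor of the programme, had 0.35 (adjusted p = 0.104), and the chaperone gene Hspa5 fell by 0.52 on the log2 scale. Among the largest rises of named genes outside the list were the glycine transporter gene Slc6a9, from 8.08 ± 1.02 to 79.8 ± 18.5 TPM (log2 fold change 3.13, adjusted p = 7.6e-08), and the peptide hormone gene Adm2, from 1.52 ± 0.40 to 22.98 ± 9.52 TPM (3.18, adjusted p = 2.2e-06). The transcription factor gene Atf5 rose from 39.8 ± 4.38 to 255 ± 37.1 TPM (2.64, adjusted p = 2.5e-09) and Stc2 from 2.93 ± 1.36 to 21.4 ± 11.3 TPM (2.46, adjusted p = 0.000128).

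Of 19 cholesterol synthesis and uptake genes, 18 fell, with a median of -0.88 and the same count when adjusted over the list alone. The list's adjusted p was 2.3e-20, and 0.0967 with an estimated correlation. Besides Idi1, the pathway regulator gene Insig1 fell from 19.2 ± 4.36 to 5.85 ± 1.30 TPM and the farnesyl diphosphate synthase gene Fdps from 73.5 ± 7.52 to 28.9 ± 3.15 TPM (SD, n = 4 each). Dhcr7 was the member that did not pass (0.09, adjusted p = 0.593).

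The hypoxia list fell with a median of -0.56 and 10 of 19 members past the threshold (11 over the list alone), at an adjusted p of 5.3e-09, and 0.234 with an estimated correlation. Ankrd37 fell from 14.2 ± 4.81 to 3.08 ± 1.01 TPM, the carbonic anhydrase gene Car9 from 8.12 ± 2.01 to 2.69 ± 0.74 TPM, the mitophagy receptor gene Bnip3 from 40.7 ± 5.55 to 16.7 ± 4.77 TPM and the prolyl hydroxylase gene Egln3 from 109 ± 8.96 to 45.9 ± 5.11 TPM (SD, n = 4 each). The glucose transporter gene Slc2a1 (-1.02), Ldha (-0.83) and Pgk1 (-0.92) fell too. Vegfa had 164 ± 41.9 TPM in vehicle and 110 ± 22.5 TPM at 50 mg/kg (adjusted p = 0.139). Outside the list, the lactate transporter gene Slc16a3 fell from 17.4 ± 3.67 to 3.84 ± 0.64 TPM (adjusted p = 3.4e-05), Prss35 from 5.35 ± 1.93 to 0.83 ± 0.22 TPM and Aire from 27.2 ± 20.6 to 3.75 ± 3.11 TPM (adjusted p = 0.00936).

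All 32 proliferation genes had negative log2 fold changes (median -0.57), and 15 passed (28 over the list alone). The list's adjusted p was 6.2e-16, and 0.486 with an estimated correlation. The replication helicase genes Mcm5 (62.6 ± 9.04 to 32.7 ± 4.94 TPM) and Mcm4 (48.0 ± 7.34 to 26.5 ± 1.99 TPM) and the cyclin gene Ccnb2 (57.9 ± 2.44 to 32.2 ± 3.75 TPM) fell, and Mki67 fell from 135 ± 21.5 to 90.3 ± 11.3 TPM (SD, n = 4; adjusted p = 0.0451), a call lost in 9 of 23 alternatives. The erythroid list had a median of -1.77 and an adjusted p of 0.000734, and 0.486 with an estimated correlation (exact permutation p = 0.143). The mean log2 level of this list was 4.40 in 50 mg/kg replicate 4, above the vehicle libraries (3.95 to 4.15), and 1.44 to 2.32 in the others at 50 mg/kg. Its 6 members all passed over the list alone but only Tfrc, the transferrin receptor gene, over all genes (-1.10, adjusted p = 0.00304). Macrophage genes had a median of 0.63, with an adjusted p of 0.00518, and 0.996 with an estimated correlation. Of its 25 members, 1 passed, and the list did not pass without vehicle replicate 4 (adjusted p = 0.0839) or 50 mg/kg replicate 1 (0.162).

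The remaining 24 lists did not pass on day 4, with adjusted p between 0.133 and 0.997. Other scalings gained some: type I interferon with TMM factors (0.0340), and T and NK cells (0.0299), type I interferon (0.0299), interferon-gamma (0.0415) and immediate early genes (0.0459) after quantile normalization. Both interferon lists passed without vehicle replicate 1 (0.0234 and 0.0292) and muscle without vehicle replicate 4 (0.0426). They covered Wnt targets and components, p53 targets, luminal, basal, milk, squamous and mesenchymal genes, fibroblasts, endothelium, T cells, both interferon lists, neutrophils, dendritic cells, B cells, mast cells, adipocytes, muscle, nerve, immediate early genes, Notch, Hedgehog and xenobiotic genes. Single members passed, among them the hemidesmosome gene Itgb4 (0.65), the transcription factor gene Snai2 (0.46), the cornified envelope gene Tgm1 (0.89), the frizzled receptor gene Fzd1 (0.72), Pmp22 (0.96) and Klf6 (0.81), which rose, and the quinone reductase gene Nqo1 (-0.63), which fell. Further members that rose were the pro-apoptotic gene Bcl2l11 (0.48) and Trp53inp1 (0.45) of the p53 list, Plin2 (0.62), Sbsn (0.88), the checkpoint receptor gene Havcr2 (0.79), Ctgf (0.69) and Hes1 (0.29), and Mcm3 (-0.75), Sox10 (-0.30), Smo (-0.21) and Txnrd1 (-0.37) fell. Of 23 alternatives (22 for Havcr2), 13 ended the call of Ctgf, 12 Hes1, 11 Smo, 10 Sox10, 9 each Havcr2 and Sbsn, 8 Bcl2l11, 6 Trp53inp1, 5 Mcm3, and 4 each Txnrd1 and Tgm1. In lists without a passing member, the smallest p belonged to genes such as Areg (0.76, adjusted p = 0.0734) and Krt19 (2.16, 0.110) of the luminal list, Tgfbi (0.81, 0.0790) and Twist1 (-0.28, 0.148) of the mesenchymal, and Pdgfrb (0.46, 0.0690) and Thy1 (0.28, 0.476) of the fibroblast list. Among immune cells they were Tap2 (0.39, 0.181), Tapbp (0.40, 0.232), Usp18 (0.87, 0.237), Rsad2 (0.88, 0.277), Tnf (0.80, 0.105), Clec4d (0.90, 0.187), Fscn1 (-0.55, 0.0801), Itgax (0.68, 0.129), Derl3 (-0.48, 0.106), Pou2af1 (-0.45, 0.205), Hdc (0.47, 0.256) and Tpsb2 (0.34, 0.642). For adipocytes and muscle they were Cidea (0.74, 0.146), Lipe (0.44, 0.214), Ckm (1.94, 0.434) and Tnni2 (1.11, 0.492). The direction of the list test differed from the sign of the median for milk proteins (median -0.22, test upward), B cells (0.04, downward) and xenobiotic genes (0.09, downward), and for Notch the mean was -0.04 with a test upward. Rn7s2, a copy of the 7SL RNA, also fell (-4.10, adjusted p = 0.0206), listed at 0 in 3 of the 4 libraries at 50 mg/kg, a call lost in 5 of 22 alternatives. Its value is uncertain because near-identical copies share reads.

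The count of 1457 was 3205 with library weights, and it was 699 without 50 mg/kg replicate 3, 780 without vehicle replicate 3, 869 without vehicle replicate 1 and 881 without vehicle replicate 4. Quantile normalization called 656 higher and 873 lower. Of the genes named here for any comparison, Acta1, Aldh1l2, Ankrd37, Atf5, Atp2a1, Car9, Ccnd1, Ctgf, Ctnnb1, Ddit3, Dll4, Dvl2, Gli1, Irf7, Lipe, Mbp, Nusap1, Shmt2, Slc6a9, Tapbp and Tnnc2 overlap a gene with a mean of 1 TPM or more on the opposite strand, and Fdps, Sbsn, Smo and Tapbp one on the same strand, so their values are uncertain. Partners with a higher mean than the gene itself lay opposite Aldh1l2, Ankrd37, Atf5, Atp2a1, Ddit3, Dvl2, Gli1, Irf7 and Tnnc2.

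**Figure D1:**
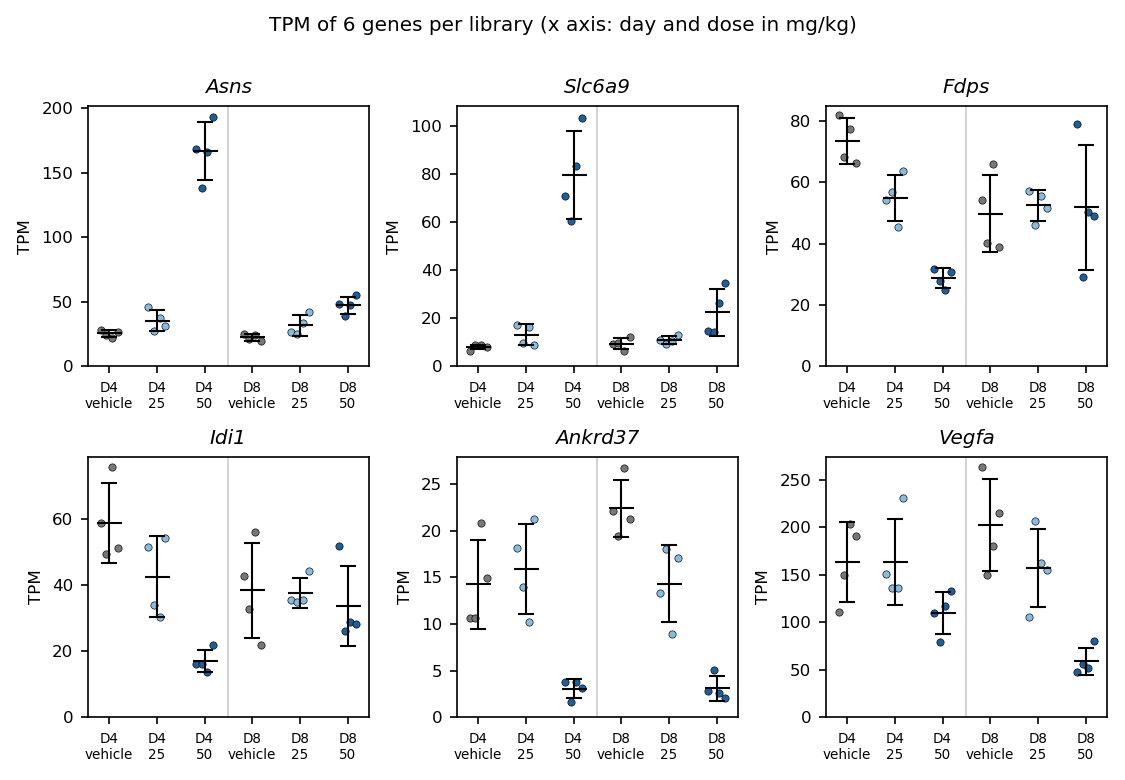
TPM of 6 genes (y axis, linear, from 0) in each library of the 6 groups (x axis: day and dose in mg/kg). Points are libraries, and bars are the mean with the SD (n = 4); Asns reached 166 TPM at 50 mg/kg on day 4 and 47.5 TPM on day 8, while Ankrd37 was at 3.08 and 3.13 TPM.

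After 7 days at 50 mg/kg, the genes of the hypoxia list stood out: the growth factor gene Vegfa fell from 202 ± 48.7 to 58.8 ± 14.6 TPM (SD, n = 4; log2 fold change -1.76, SE 0.24, adjusted p = 0.000313). The keratin genes Krt14, Krt17 and Krt5 rose, and the vessel genes Dll4, Notch4 and Apln fell. The comparison asks what the higher dose changed at the later time. By limma, 438 genes passed, 120 higher and 318 lower, and 67 of these changed at least 2-fold.

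In the hypoxia list, 14 of 19 genes fell (16 over the list alone), with a median of -0.85 and an adjusted p of 7.9e-20, and 0.0385 with an estimated correlation. With the replicate number as a block as well, the latter was 0.146. Ankrd37 fell from 22.4 ± 3.07 to 3.13 ± 1.34 TPM, Bnip3 from 56.6 ± 14.6 to 14.6 ± 3.74 TPM and Car9 from 9.38 ± 2.45 to 2.61 ± 1.74 TPM (SD, n = 4 each). Outside the list, Slc16a3 fell from 21.8 ± 7.52 to 5.03 ± 1.91 TPM, the cytochrome oxidase subunit gene Cox4i2 from 11.5 ± 1.60 to 3.11 ± 0.75 TPM, Prss35 from 5.74 ± 2.07 to 0.69 ± 0.18 TPM and Aire from 28.7 ± 9.65 to 2.62 ± 1.92 TPM (adjusted p = 0.00396). Tfrc fell by 0.94 on the log2 scale (adjusted p = 0.0196).

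Of 20 basal and myoepithelial genes, 5 rose and none fell, while 10 log2 fold changes were positive and 10 negative (median 0.01). The list's adjusted p was 0.0118, and 0.676 with an estimated correlation; it was 0.112 without vehicle replicate 3 and 0.134 without 50 mg/kg replicate 2, and the median ranged from -0.047 to 0.10 without single libraries. The basal keratin gene Krt14 rose from 846 ± 140 to 1561 ± 518 TPM (adjusted p = 0.0103), Krt17 from 392 ± 104 to 755 ± 224 TPM and Krt5 from 554 ± 102 to 785 ± 88.5 TPM (SD, n = 4 each), with Itgb4 (0.47) and Snai2 (0.39). Of the 18 squamous differentiation genes, the calmodulin-like gene Calml3 rose from 410 ± 87.0 to 750 ± 198 TPM and Flg, which several annotated gene identifiers share, fell from 14.9 ± 5.56 to 2.41 ± 2.89 TPM. That list's adjusted p was 0.0300, and 0.723 with an estimated correlation. The call also ended with TMM factors (0.105), after quantile normalization (0.0602) and without the length trend (0.0963), and without vehicle replicate 2 (0.229), vehicle replicate 4 (0.0881) or 50 mg/kg replicate 4 (0.417, median -0.0019). Among genes that passed and met the naming rule, the largest rises were Wfdc12, from 4.75 ± 2.16 to 31.5 ± 12.7 TPM (log2 fold change 2.49, adjusted p = 0.000226), and Dapl1, from 14.0 ± 3.46 to 54.2 ± 19.1 TPM (1.85). They were followed by the tight junction gene Cldn11, from 2.398 ± 1.54 to 10.4 ± 2.35 TPM (1.83), and the glutathione transferase gene Gsta4, from 78.1 ± 24.1 to 215 ± 71.4 TPM (1.44). Ttc36 (1.41), the aquaporin gene Aqp3 (1.40), Aox3 (1.17) and the defensin gene Defb1 (1.11) rose as well.

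Endothelial genes had a median of -0.50, with an adjusted p of 0.000152, and 0.676 with an estimated correlation. Without vehicle replicate 4 the median was -0.34 and the mean -0.24, against a mean of -0.46 with it, and the list did not pass (adjusted p = 0.0539). Of 20, only the peptide gene Apln passed (7.70 ± 1.41 to 3.25 ± 0.82 TPM, SD, n = 4), and 8 did over the list alone. The Notch ligand gene Dll4 (9.92 ± 4.90 to 3.38 ± 0.49 TPM) and the receptor gene Notch4 (10.9 ± 3.91 to 4.995 ± 1.54 TPM), both active in vessels, fell, although the Notch list had an adjusted p of 0.248. In the integrated stress response list, Asns rose from 22.5 ± 2.68 to 47.5 ± 6.57 TPM (adjusted p = 0.00109) and Herpud1 from 58.9 ± 15.0 to 108 ± 30.8 TPM, and the lipoprotein receptor gene Vldlr fell from 13.1 ± 2.29 to 7.43 ± 0.44 TPM. Its median was 0.22 and its adjusted p 0.0118, and 0.676 with an estimated correlation, 0.0625 without vehicle replicate 2 and 0.108 without vehicle replicate 4. The median was 0.10 without 50 mg/kg replicate 4 and 0.15 without 50 mg/kg replicate 1. No proliferation or cholesterol synthesis gene passed (list adjusted p 0.801 and 0.283), except Mki67 and Nusap1 with library weights. Both lists depended on single libraries: without vehicle replicate 4 their medians were -0.27 (adjusted p = 5.1e-05) and -0.22 (0.0477), and without 50 mg/kg replicate 1 they were -0.19 (0.0162) and -0.28 (0.00228). Without vehicle replicate 3 the proliferation list passed upward (0.08, 0.0291).

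Immune lists had positive medians with the preset correlation: type I interferon response 0.59 (adjusted p = 0.000152), interferon-gamma and antigen presentation 0.46 (7.1e-06), B and plasma cells 0.46 (0.0164), macrophages 0.39 (0.000134) and T and NK cells 0.33 (0.00954). With an estimated correlation their adjusted p lay between 0.676 and 0.704, and Xbp1, which secretory epithelium also expresses, was the only member past the threshold (0.45). Single libraries carried some of these values. Without 50 mg/kg replicate 4 the type I interferon median turned to -0.08 (adjusted p = 0.948) and the interferon-gamma median fell to 0.17. Without vehicle replicate 1 the macrophage median was 0.23, and without vehicle replicate 2 T and NK cells did not pass (0.0719). B and plasma cells did not pass without 50 mg/kg replicate 1 (0.0793) or 2 (0.0570), nor with protein-coding genes rescaled (0.0615). Without vehicle replicate 4 the medians of the interferon, macrophage and T cell lists were higher, 0.59 to 0.91, and without 50 mg/kg replicate 2 type I interferon was at 0.98. Within the vehicle group of day 8, the mean log2 level of the macrophage list was 5.46 in replicate 4 and 4.11 to 4.87 in the others. The remaining 20 lists did not pass, with adjusted p from 0.0967 for skeletal muscle to 1.00 for the luminal list. Without vehicle replicate 4, neutrophils (median 0.75, 0.000203) and dendritic cells (0.00751) passed as well, and neutrophils also without 50 mg/kg replicate 1 (0.00365). Muscle passed without each of 3 libraries (lowest adjusted p = 0.000503), immediate early genes without each of 3 (0.00339) and fibroblasts without 50 mg/kg replicate 4 (0.0277).

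Among lists that did not pass on day 8, the cytokine gene Csf3 (1.06, adjusted p = 0.0162), Ctgf (0.89, 0.0276) and the sulfiredoxin gene Srxn1 (0.73, 0.0333) rose. Without a passing member, the smallest p in the tumour cell lists belonged to Foxa1 (0.92, 0.0673), Ltf (1.56, 0.126), Csn3 (1.22, 0.0537), Xdh (0.78, 0.188), Bcl2 (-0.47, 0.0630), Nusap1 (-0.25, 0.504), Lss (-0.38, 0.232), Gli1 (0.77, 0.169) and Gli3 (0.10, 0.599). In immune lists it belonged to Trbc2 (1.40, 0.0803), Havcr2 (0.65, 0.106), Ccl5 (2.04, 0.104), H2-D1 (0.46, 0.123), Bst2 (0.83, 0.214), Irf7 (1.14, 0.309), Trem2 (0.87, 0.122), Spp1 (1.17, 0.184), Fscn1 (-0.58, 0.109), Kit (-0.34, 0.427) and Hdc (0.03, 0.968). In the other tissue lists it belonged to Col12a1 (-0.72, 0.399), Fbln1 (0.23, 0.496), Lpl (0.71, 0.456), Cidea (-0.21, 0.786), Atp2a1 (1.35, 0.622), Tnnc2 (1.31, 0.677), Sox10 (-0.28, 0.0805) and Mbp (-0.36, 0.199). The median and the test differed in sign for milk proteins (-0.05, test upward), fibroblasts (-0.01, upward), mast cells (0.01, downward) and adipocytes (-0.06, upward), and the median and the mean for Wnt targets (-0.06 and 0.01), mesenchymal (0.01 and -0.01) and nerve genes (-0.09 and 0.02).

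The count of 438 was 12 when the 2 groups were fitted alone and 2888 with library weights, and it was 180 without 50 mg/kg replicate 3, 207 without vehicle replicate 1, 214 without vehicle replicate 2 and 1175 without vehicle replicate 4. It was split 206 higher and 215 lower with TMM factors, 169 and 279 after quantile normalization and 203 and 203 without the length trend, and of the genes named for this day Herpud1 lost its call in 12 of 23 alternatives, Itgb4 and Xbp1 in 10, Krt5, Srxn1, Ctgf and Aox3 in 9, and Krt17, Tfrc and Vldlr in 5, and Csf3 in 5 of 22, while Aire, Ankrd37, Asns, Bnip3, Cox4i2, Prss35 and Vegfa passed in each of 23 alternatives.

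**Figure D2:**
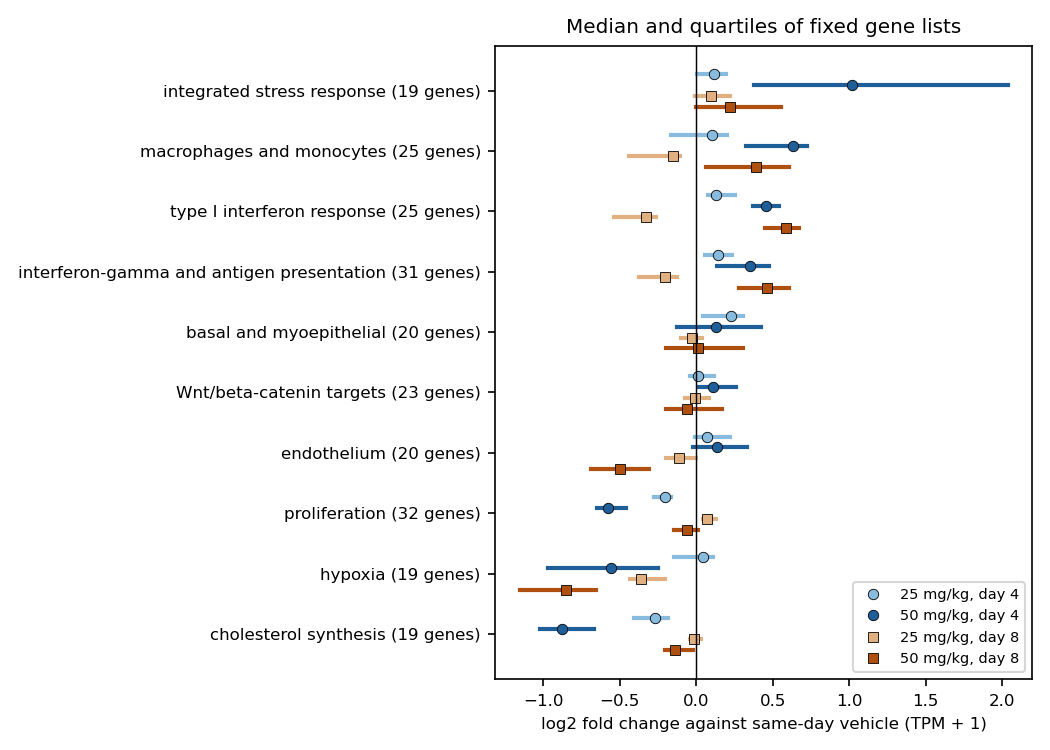
Median log2 fold change (points) and quartiles (lines) of 10 gene lists against the vehicle group of the same day (x axis, log2 of TPM + 1), for both doses and days. At 50 mg/kg the hypoxia median was -0.56 on day 4 and -0.85 on day 8, and the cholesterol synthesis median was -0.88 and -0.14.

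Transcription of Wnt/β-catenin target genes was examined because the tumours are driven by Wnt1 and the compound is directed at β-catenin and CBP. Axin2, a feedback target of the pathway, was at 48.2 ± 6.31 TPM in vehicle and 48.6 ± 10.7 TPM at 50 mg/kg on day 4 (adjusted p = 0.988), and at 39.0 ± 7.03 and 34.5 ± 7.26 TPM on day 8 (adjusted p = 0.598; SD, n = 4 each). The 23 measured targets had medians of 0.11 on day 4 and -0.06 on day 8, and the list did not pass by camera (adjusted p = 0.361 and 0.778). On day 4 fry gave a directional adjusted p of 0.0519. The mixed form of fry passed on both days (adjusted p = 0.00105 and 0.00124), as members moved in either direction. The mean level of the list in each of the 4 libraries at 50 mg/kg on day 4 lay above all 4 vehicle libraries (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.122). With that smallest p, a list could pass after adjustment only if most lists came near it too, so the adjusted value does not decide. The Wnt deacylase gene Notum (15.4 ± 4.68 to 31.1 ± 7.66 TPM, adjusted p = 0.0269) and the secreted inhibitor gene Wif1 (237 ± 22.0 to 379 ± 93.7 TPM, adjusted p = 0.0138) rose on that day, and the cyclin gene Ccnd1 fell (667 ± 17.9 to 524 ± 20 TPM, adjusted p = 0.0351). Nkd1, another feedback inhibitor, was at 10.2 ± 0.92 and 10.5 ± 1.12 TPM on day 4 (adjusted p = 0.835) and fell from 9.16 ± 0.23 to 6.95 ± 0.83 TPM on day 8 (adjusted p = 0.0302). These calls were lost in 7 (Notum), 2 (Wif1), 11 (Ccnd1) and 12 (Nkd1) of 23 alternatives.

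Wnt1 itself was at 128 ± 26.1 and 116 ± 17.98 TPM in vehicle and 50 mg/kg tumours on day 4 (adjusted p = 0.807), and at 141 ± 41.4 and 93.5 ± 49.5 TPM on day 8 (adjusted p = 0.231; SD, n = 4 each). Ctnnb1, the β-catenin gene, had log2 fold changes of 0.21 and -0.11 on the 2 days (adjusted p = 0.166 and 0.607). Crebbp, the CBP gene, had 0.12 and -0.06 (0.501 and 0.834), and the related coactivator gene Ep300 0.19 and -0.06 (0.244 and 0.796). Lef1 stayed below 2 TPM as a mean in every group named here, with 0.46 ± 0.16 and 1.47 ± 1.04 TPM on day 4 (adjusted p = 0.103) and 0.66 ± 0.45 and 0.81 ± 0.41 TPM on day 8 (0.820). Cd8a, a gene of cytotoxic T cells, was below the filter, with group means of 0.11 to 0.26 TPM in these 4 groups. The list of Wnt pathway components had adjusted p of 0.617 on day 4 and 0.717 on day 8. Fzd2, Dvl2 and Wls moved by less than 0.30 on day 4 (calls lost in 7, 13 and 15 of 23 alternatives), as did the kinase gene Gsk3b on day 8 (-0.29, adjusted p = 0.0238; lost in 7 of 23).

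**Figure D3:**
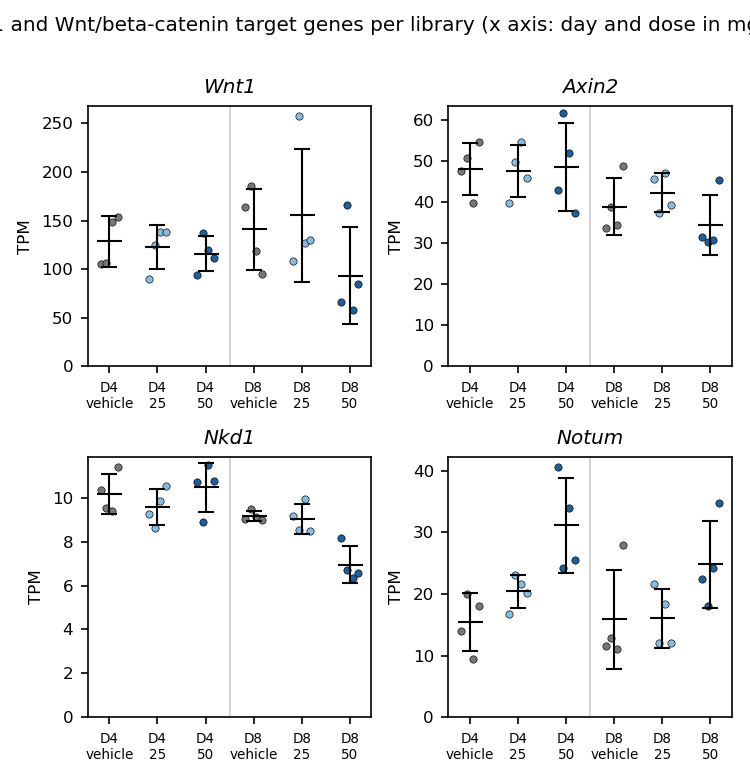
TPM of Wnt1 and 3 Wnt/β-catenin target genes (y axis, linear, from 0) in each library of the 6 groups (x axis: day and dose in mg/kg). Points are libraries and bars the mean with the SD (n = 4); Axin2 means lay between 34.5 and 48.6 TPM, and Nkd1 was lowest at 50 mg/kg on day 8 (6.95 TPM).

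At 25 mg/kg no gene passed on either day, which is the comparison of the lower dose with vehicle. Asns was at 35.5 ± 7.91 TPM on day 4 (log2 fold change 0.44, adjusted p = 0.914) and 31.8 ± 7.90 TPM on day 8 (0.46, adjusted p = 1.00), and Idi1 was at 42.7 ± 12.2 TPM on day 4 (-0.48, adjusted p = 0.914; SD, n = 4 each). At an unadjusted p under 0.05 limma found 724 genes on day 4 and 468 on day 8, and each other setting called 0 or 1. With the preset correlation 11 lists passed on day 4. Cholesterol synthesis (median -0.27, adjusted p = 1.6e-07), proliferation (-0.20, 1.2e-08), erythroid (-1.09, 0.00128) and adipocyte genes (-0.78, 0.0126) were lower. Luminal (0.25, 0.000717), basal (0.23, 0.0126), squamous (0.32, 0.00839), muscle (1.06, 0.00128), neutrophil (0.26, 0.0475), Wnt component (0.07, 0.0188) and integrated stress response genes (0.12, 0.0475) were higher. None of the 11 passed with an estimated correlation (lowest adjusted p = 0.847). Leaving out 1 library ended the calls of adipocytes (vehicle replicate 1, 0.351), basal (vehicle 4, 0.177; 25 mg/kg 2, 0.0567), squamous (vehicle 1, 0.0956; 25 mg/kg 1, 0.0781) and Wnt component genes (vehicle 4, 0.0595; 25 mg/kg 2, 0.0567). Neutrophil and stress response genes did not pass without each of 4 libraries (highest adjusted p = 0.489 and 0.203). Of the 19 other lists, 7 passed without 1 library or another, as did 7 of 23 on day 8. On day 8, 7 lists passed: all 19 hypoxia genes had negative values (median -0.36, adjusted p = 7.0e-13). Type I interferon (-0.33, 0.000953), interferon-gamma (-0.20, 0.000953), macrophage (-0.15, 0.0114), neutrophil (-0.22, 0.0114) and immediate early genes (-0.15, 0.000953) were lower. Proliferation genes were higher (0.07, 0.0342). With an estimated correlation the lowest adjusted p was 0.199, for hypoxia. The immune values rested on vehicle replicate 4. Without it the medians were 0.06 for interferon-gamma, -0.06 for type I interferon, 0.0025 for macrophages and 0.21 for neutrophils, and none of the 4 passed (adjusted p = 0.531, 0.531, 0.874 and 0.578), while proliferation genes turned to -0.12 (0.00110). Macrophage genes also did not pass without vehicle replicate 3 (0.194) or 25 mg/kg replicate 2 (0.203), nor neutrophil genes without the latter (0.127). Without vehicle replicate 1 the 4 medians lay between -0.36 and -0.51, and without vehicle replicate 2 the neutrophil median was -0.60. The proliferation list did not pass without vehicle replicate 2 (0.232), 25 mg/kg replicate 1 (0.143) or 4 (0.351). The proliferation call also ended with TMM factors (0.0761), after quantile normalization (0.0525) and without the length trend (0.0941), and immediate early genes did not pass without vehicle replicate 1 (0.0625) or 25 mg/kg replicate 2 (0.122).

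The log2 fold changes of the 2 doses against the same vehicle libraries had a correlation across genes of 0.554 on day 4 and 0.330 on day 8, where genes are not independent replicates. Unchanged groups simulated against shared controls gave 0.503 and 0.498. The covariance was 0.0391 on day 4 against 0.0256 simulated, and 0.0186 on day 8 against 0.0254 simulated. With the vehicle libraries divided between the doses, the mean correlation over 6 divisions was 0.223 on day 4 and -0.122 on day 8.

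Compared directly, 11 of 19 stress response genes were higher and 8 of 19 cholesterol synthesis and 8 of 19 hypoxia genes were lower at 50 than at 25 mg/kg on day 4, with 339 genes past the threshold (181 higher, 158 lower). Asns was at 166 against 35.5 TPM (log2 fold change 2.21, adjusted p = 3.0e-08), with Slc6a9 (2.53), Adm2 (2.46) and Chac1 (2.38) higher, and Ankrd37 (-2.04), Slc16a3 (-1.78) and Prss35 (-1.75) were lower. The integrated stress response list (15 genes higher over the list alone) had an adjusted p of 1.5e-19, and 0.0117 with an estimated correlation. Cholesterol synthesis and hypoxia genes had adjusted p of 1.5e-19 and 6.1e-13, both 0.0779 with an estimated correlation. On day 8, 170 genes passed (36 higher, 134 lower). Wfdc12 (1.995), the lymphocyte activation gene Cd69 (1.93), Cldn11 (1.63) and Dapl1 (1.42) were higher, and Aire (-2.86), Flg (-2.35), Ankrd37 (-1.90), Prss35 (-1.89) and Vegfa (-1.39) were lower. The calls of Cd69 (6 of 22 alternatives), Flg (5 of 23), Aire (4), Cldn11 (3) and Dapl1 (2) were lost in some. Of the 19 hypoxia genes 6 were lower, at an adjusted p of 4.2e-10, and 0.473 with an estimated correlation. The type I interferon list had a median of 1.05 (adjusted p = 4.2e-10, and 0.489 with an estimated correlation) with no member past the threshold. Without 50 mg/kg replicate 4 that median was 0.26 (adjusted p = 0.00162). In all, 12 lists passed with the preset correlation, and 5 of them did not without 1 library or another. Among those that passed without each library in turn, still with the preset correlation, were interferon-gamma (median 0.70, at its weakest 0.44), macrophage (0.70, 0.54) and neutrophil genes (0.69, 0.45). These were higher. T and NK cell genes (0.45, 0.36) were higher as well, and endothelial genes (-0.39, -0.31) were lower. For these lists the test with an estimated correlation is not given here.

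The 339 genes of day 4 were 219 in a fit of the 2 groups alone and 1263 with library weights, and 148, 193 and 207 without 25 mg/kg replicate 4, 50 mg/kg replicate 3 and 50 mg/kg replicate 4. The 170 of day 8 were 77 in a fit of the 2 groups alone, 2264 with library weights, 294 with protein-coding genes rescaled and 50 with the macrophage covariate. They were 73, 38 and 113 without 25 mg/kg replicates 2, 3 and 4, and 293 and 56 without 50 mg/kg replicates 1 and 3, and split 103 higher and 104 lower with TMM factors and 94 and 107 without the length trend.

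Vehicle tumours of day 8 and day 4 were compared to see what differed between the days without the compound. The length of vehicle dosing and the day of collection differed with them, so time alone was not set apart. No gene passed by limma (1749 at an unadjusted p under 0.05). With library weights 5 passed, and 1 did each without day 4 replicate 3 and without day 8 replicate 4. Proliferation (median -0.33, adjusted p = 7.7e-11) and cholesterol synthesis genes (-0.33, 2.9e-07) were lower on day 8, and basal (0.34, 0.00378), hypoxia (0.28, 0.000563), luminal (0.22, 0.0168), neutrophil (0.48, 0.00475) and immediate early genes (0.25, 0.00433) were higher. With an estimated correlation none passed (lowest adjusted p = 0.689). Without day 8 replicate 4 the neutrophil median was -0.0050 (adjusted p = 0.733), the proliferation median -0.13 (0.0238) and the immediate early median 0.05. The neutrophil median was 0.30 without day 4 replicate 4 and 0.92 without day 8 replicate 2. Luminal genes did not pass without day 4 replicate 4 (0.0662) or day 8 replicate 3 (0.102), nor immediate early genes without day 8 replicate 1 (0.0550). Wnt targets passed without the length trend (median -0.12, 0.0450), and without day 4 replicate 1 (0.0405) or 3 (0.0420) or day 8 replicate 1 (0.0464).

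The effect of 50 mg/kg differed between the days for 226 genes, 55 with a higher and 171 with a lower value on day 8, among them 7 of 19 stress response genes, all lower, and 5 of 19 cholesterol synthesis genes, all higher. Both lists passed with the preset correlation (adjusted p = 3.6e-10 and 9.7e-17), and not with an estimated correlation (0.181 each). The hypoxia list, which did not pass, did so with TMM factors (0.0214), after quantile normalization (0.0185) and without the length trend (0.0110), and without each of 6 of the 16 libraries (lowest adjusted p = 0.00139). Adm2 (-2.78), Stc2 (-2.65), Slc6a9 (-2.03) and Trib3 (-1.84) had the largest negative differences of log2 fold changes among genes that passed and met the naming rule, and Wfdc12 (2.66), the cornified envelope gene Ivl (2.10) and the casein gene Csn3 (1.95) were among the largest positive. Calls were lost in 14 (Csn3), 10 (Ivl) and 6 (Trib3) of 31 alternatives. Idi1 (1.58) was at 38.5 ± 14.5 TPM in vehicle and 33.8 ± 12.1 TPM at 50 mg/kg on day 8 (SD, n = 4). Of the genes that passed on each day, 37 were higher on both against 5.94 expected from independent lists, and 72 were lower on both against 13.7. The difference between the days for 25 mg/kg gave 0 genes (810 at an unadjusted p under 0.05; 1 without day 8 vehicle replicate 3; 0 by every other setting).

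The 226 genes were 149 with TMM factors (72 higher, 77 lower), 130 without the length trend (53 and 77), 68 in a fit of the 4 groups alone and 745 with library weights, and quantile normalization split them 59 and 98. They were 92, 143 and 140 without day 4 vehicle replicates 1, 2 and 3, 150, 101 and 136 without day 4 50 mg/kg replicates 2, 3 and 4, 113 and 601 without day 8 vehicle replicates 2 and 3, and 125, 129 and 471 without day 8 50 mg/kg replicates 1, 3 and 4.

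For reference, the genes named most often lie on GRCm38 as follows, counted from 1. Asns spans chromosome 6, 7675169 to 7693254, and Ankrd37 chromosome 8, 45996902 to 46005707. Vegfa lies on chromosome 17, 46016993 to 46032369, Axin2 chromosome 11, 108920349 to 108950783, and Wnt1 chromosome 15, 98789857 to 98793837, all protein-coding. Their identifiers are ENSMUSG00000029752, ENSMUSG00000050914, ENSMUSG00000023951, ENSMUSG00000000142 and ENSMUSG00000022997.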

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

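Of the tests in this part, the comparisons with the immediate early list and the sizes of the calls that ended without the length trend were chosen after the results were seen; the others were written before their values.

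The effect of 50 mg/kg on integrated stress response genes was larger on day 4 than on day 8. Of 19 list members 7 passed limma's test of the difference of log2 fold changes, among them Trib3 (-1.84), Slc7a11 (-1.73), Asns (-1.61) and Vldlr (-1.13). The list had a median of -0.98 (adjusted p = 3.6e-10, and 0.181 with an estimated correlation). A single library was argued against, since the median stayed at -0.83 or lower without each of the 16 libraries. Scaling of the values to a fixed sum was argued against likewise, since the median stayed at -0.90 or lower under 3 other scalings. These are relative too and could not show a change of total RNA. For the rise on day 4, the upper quartile of the immediate early genes, 0.34, lay below 0.51, which is 1 part in 2 of the stress list's median. This met the bound set against stress during tissue collection. The bound assumes that such stress would move both lists in proportion, which was not tested. As the immediate early list passed on day 4 after quantile normalization, such stress was not excluded. For the difference between the days it stays open, since immediate early genes moved the same way (median -0.41, mean -0.47, against a mean of -0.92 for the stress list) and their lower quartile, -0.59, lay past the bound of -0.49. Whether the response fades with repeated dosing or the time from the last dose to collection differed between the days stays open, since the labels give no such time.

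Outside that list, Adm2 (-2.78), Stc2 (-2.65), Slc6a9 (-2.03) and Atf5 (-1.66) had lower log2 fold changes on day 8. Other genes whose response to 50 mg/kg differed between the days were Idi1 (1.58), Fdps (1.33), Wfdc12 (2.66), Dapl1 (1.93), Gsta4 (1.55) and Nqo1 (0.54), all with higher log2 fold changes on day 8. Among lists, the medians of the difference were 0.68 for cholesterol synthesis, 0.48 for proliferation, -0.69 for endothelium and -0.41 for immediate early genes. Without day 8 vehicle replicate 4 they were 0.27 for proliferation, -0.44 for endothelium and -0.28 for immediate early genes. These lists passed with the preset correlation (adjusted p = 9.7e-17, 6.8e-13, 0.000786 and 0.00365) and none did with an estimated one, where the lowest adjusted p among the lists was 0.181.

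Single libraries lay far from the other 3 of their group, by a gap over 0.83 of the group's range. Chance gives that in about 1 of 20 groups, and it was found in 6 of 206 gene groups and 5 of 42 groups of library measures. Rn7s2 was at 23.72 TPM in day 4 50 mg/kg replicate 3 and listed at 0 in the others. Axin2 was at 45.4 TPM in day 8 50 mg/kg replicate 4, against 30.4 to 31.5 TPM. Notum was at 27.92 TPM in day 8 vehicle replicate 4, against 11.1 to 12.9 TPM. Sox10 was at 325.22 TPM in day 4 vehicle replicate 4, Srxn1 at 12.43 TPM in day 8 vehicle replicate 4, and Prss35 at 0.96 TPM in day 8 50 mg/kg replicate 4. The mean log2 level of skeletal muscle genes was 3.3493 in day 4 vehicle replicate 4, where the others had 0.779 to 0.924, and 3.7658 in day 8 vehicle replicate 3, where the others had 0.832 to 1.31. Ribosomal protein genes took 11.569% of the TPM total in day 4 25 mg/kg replicate 1 and 13.5% to 13.6% in the others. Genes at 1 TPM or more numbered 14973 in day 4 25 mg/kg replicate 1 and 14985 in day 4 50 mg/kg replicate 1, each above the rest of its group.

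Other divisions of the same libraries into groups of equal size were tried. For 50 mg/kg against vehicle on day 4, 1 of 35 splits, the real one with 1457 genes, gave as many, and the highest other gave 1. This argues against chance without excluding it. A share of 1 of 35 is the smallest that the test allows, and it was not adjusted over the comparisons. On day 8 chance was not excluded, because 4 of 35 splits gave 438 genes or more, up to 1653. The split with 1653 set vehicle replicates 1, 2 and 3 with 50 mg/kg replicate 1 against the rest. It exchanged only vehicle replicate 4 and 50 mg/kg replicate 1, so it still holds much of the dose. A structure of these samples besides the dose is possible. On the first principal component, with 18.2% of the variance, vehicle replicate 4 lay at 28.2 and the other vehicle libraries at -25.5, -15.7 and -23.1. The 50 mg/kg replicates 1 to 4 lay at 7.73, -1.70, 24.6 and 30.8. As replicate 1 lay above replicate 2, the component does not reproduce that split in full. For 50 against 25 mg/kg, the real split gave the most genes on both days, each 1 of 35 with the same limit. It gave 339 genes against at most 6 on day 4, and 170 against at most 31 on day 8. For the difference of the 50 mg/kg effect between the days, 3 of 100 drawn splits of 2450 gave 226 genes or more, the real one included, a share under 5% whose 95% interval, 0.623% to 8.52%, spans 5%, so chance was not firmly excluded. The highest other, with 1887, exchanged the doses of all day 4 libraries alone, which adds the effects of both days instead of setting them apart, and so points to the dose. For the comparisons with 0 genes every split gives as many, so the test could not decide there. It gave 35 of 35 for 25 mg/kg on day 4 (highest other 1) and 35 of 35 on day 8 (8). For the vehicle groups it gave 35 of 35 (1), and for the 25 mg/kg difference 100 of 100 (2).

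The fold changes at 50 mg/kg followed transcript length across genes, with a Spearman correlation of 0.129 on day 4 and -0.0834 on day 8, where genes are not independent replicates. After each library's trend with length was removed, 87.9% of the genes called on day 4 were still called (1280 genes), which argues against length as the cause of most of that day's calls. On day 8 it was 73.7% (323 genes), between the bounds set for either answer. The 115 calls that ended kept a median of 0.846 of their log2 fold change, and none turned, so their loss does not by itself speak for length as the cause, which stays open.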

How the results depend on the processing

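Of the alternatives here, the rescaling of protein-coding genes, the removal of the length trend and the muscle and macrophage covariates, and leaving out libraries for every list, were chosen after the data were seen. The cause of the differences was not tested except where fewer libraries or a 2-fold minimum set it. No named gene that passed changed sign under any alternative, and the median log2 fold change of all genes was at most 0.0813 in size under any alternative. Read depth, which limits low genes most, is unknown.

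Counts of genes for 50 mg/kg against vehicle were 3205 on day 4 and 2888 on day 8 with library weights, and 12 on day 8 in a fit of the compared groups alone. At least 2-fold changes numbered 110 and 67 against vehicle, 58 and 31 against 25 mg/kg, and 51 for the difference between days. For 50 against 25 mg/kg, fits of the compared groups alone gave 219 and 77, library weights 1263 and 2264, and on day 8 rescaling of protein-coding genes 294 and the macrophage covariate 50. The difference between days for 50 mg/kg was 149 with TMM factors, 68 with its groups alone, 745 with weights and 130 without the length trend. Counts of 0 became 1 for 25 mg/kg on day 4 with weights, 1 on day 8 with weights and with its groups alone, and 5 for the vehicle groups with weights. Leaving out each library in turn gave 699 to 1311 and 180 to 1175 for 50 mg/kg on days 4 and 8, 0 to 1 and 0 to 0 for 25 mg/kg, 148 to 356 and 38 to 293 for 50 against 25 mg/kg, 0 to 1 for the vehicle groups, 92 to 601 for the 50 mg/kg and 0 to 1 for the 25 mg/kg difference between days.

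Lists passed with the preset correlation 6, 10, 11 and 7 times (50 mg/kg on days 4 and 8, 25 mg/kg on days 4 and 8), with an estimated correlation 0, 1, 0 and 0 times, by directional fry 5, 1, 0 and 0 times and by mixed fry 11, 11, 0 and 0 times. Limma's unadjusted p-value for the Wnt target list was 0.162 on day 4 and 0.648 on day 8. On day 4 it was 0.0104 by directional and 0.000209 by mixed fry, and 0.142 to 0.263 by camera under the other settings without a block; on day 8 mixed fry gave 0.000166. In the exact permutation test, chosen after the data were seen, the stress response, cholesterol, proliferation, hypoxia, Wnt target, p53 and nerve lists on day 4 and the hypoxia and Notch lists on day 8 at 50 mg/kg, and the luminal, basal and erythroid lists at 25 mg/kg on day 4, had the smallest possible p, 0.0286. None passed after adjustment over the lists (adjusted p = 0.122, 0.429 and 0.286). With 0.0286 as the smallest possible p, a list could pass only if most lists reached or came near it at once. The adjusted permutation test could therefore hardly call a list, and its failure does not speak against any of them. Leaving out libraries for the Wnt target list gave 0.0709 to 0.298 on day 4 and 0.389 to 0.952 on day 8.

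Replicate numbers were not used as pairs in the main fit, as the labels give no pairing. The deviations of same-numbered pairs had a median correlation of 0.116, against -0.022 for other numbers. Of 24 same-numbered pairs, 12 lay over 0.1 (-0.19 to 0.421), among them all 6 of number 2. Of 24 libraries, 11 correlated best with their own number. A block shared by the number is therefore possible. With the number as a block, counts were 1803 and 656 for 50 mg/kg, 0 and 0 for 25 mg/kg, 360 and 378 for 50 against 25 mg/kg, 349 and 0 for the differences between days and 0 for the vehicle groups. Lists passed 6, 10, 12 and 7 times with the block, and the p-values of the Wnt target list were 0.155 and 0.666 (0.267 and 0.730 with an estimated correlation, 3.9e-05 and 2.8e-06 by mixed fry). The hypoxia list on day 8 had an adjusted p of 0.146 with the block and an estimated correlation.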

Other observations

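In this part, the lists of tRNA synthetases, glycolytic enzymes and vessel cells and all tests on them were chosen after the results were seen. Their p-values therefore describe these data and are no independent test. The comparison of hypoxia with epithelial genes was also chosen then, while the test of scaling was written before.

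Genes of cytosolic tRNA synthetases, which charge tRNAs with amino acids, rose at 50 mg/kg on day 4: 13 of 20 passed upward, 1 downward (Farsa, -0.32), and the median was 0.83 (adjusted p over 6 added lists 5.6e-17, and 0.0110 with an estimated correlation). Without 1 library 11 or 12 passed upward. The cysteine (Cars, 1.70), asparagine (Nars, 1.44), threonine (Tars, 1.21) and alanine (Aars, 1.18) enzymes rose most. A rise of both sets of synthetase genes was argued against, as the 17 genes listed as mitochondrial had a median of -0.029, with 1 past the threshold, downward. This compares genes and does not show in which compartment the enzymes of the cytosolic list work. On day 8 the cytosolic median was 0.13 (adjusted p = 0.000171, and 0.227 with an estimated correlation), with Cars and Nars past the threshold. This rested on single libraries: without vehicle replicate 4 the adjusted p was 0.106, and Cars and Nars each missed the threshold without any 1 of 5 of the 8 libraries. Without 50 mg/kg replicate 2, 4 members passed.

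Glycolytic enzyme genes, none of them in the hypoxia list, fell at 50 mg/kg as that list did. In all, 9 of 13 fell on day 4 (median -0.61) and 7 on day 8 (median -0.45), with adjusted p of 0.0110 and 0.0144 with an estimated correlation. Without 1 library 8 or 9 fell on day 4 and 5 to 8 on day 8. Tpi1 (-1.03 and -0.71; uncertain, as it overlaps a gene on the opposite strand) and Pfkl (-0.92 and -0.90) fell on both days. At 25 mg/kg and between the days the medians of the 2 lists lay apart, but no test compared the lists. At 25 mg/kg the glycolytic medians were -0.11 and -0.07 on days 4 and 8, and those of hypoxia 0.04 and -0.36. No gene of either list passed at this dose. On day 4, 12 of 13 glycolytic genes were negative (camera adjusted p = 0.0107, and 0.344 with an estimated correlation). On day 8, 10 of 13 were (0.0936 and 0.466). From day 4 to day 8 the effect of 50 mg/kg changed by 0.13 in the glycolytic and by -0.30 in the hypoxia list, and neither passed with the preset correlation.

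Several genes of sprouting vessel tips fell at 50 mg/kg. On day 4, 6 of 8 were negative (median -0.31) and 2 passed, Pgf (-0.69) and Apln (-0.69). Pgf passed without each library in turn, and Apln missed the threshold without any 1 of 4 of the 8. On day 8, 5 of 8 passed (median -0.78), among them Apold1 (-1.42), Dll4 (-1.20) and Apln (-1.04). The list was made after Dll4 and Apln had been seen to fall, so no p is given for it; without these 2 genes 3 of 6 passed (median -0.66). Without vehicle replicate 4, where the mean log2 level of the endothelium list was 4.30 against 3.11 to 3.61 in the others of its group, the median of the 8 was -0.67; without 1 library 4 to 7 of the 8 passed. Fewer pericytes or lower expression of these genes within them may contribute, and the values cannot tell these apart. Of 10 pericyte genes 9 were negative and 2 passed (median -0.32, camera adjusted p = 0.0764 with an estimated correlation). The median lay close to the bound of -0.3 set for fewer pericytes, and without vehicle replicate 4 it was -0.26, which did not meet it. Rgs5 (-0.90) passed without each library in turn, and Abcc9 (-0.92) missed the threshold without any 1 of 6 of the 8. Whether there were fewer endothelial cells cannot be told apart from a change within them: the 14 genes found in all endothelium had a median of -0.54 with no member past the threshold, which met the bound for a loss of cells (at or below -0.52) and also the bound against it (a lower quartile, -0.65, above the tip median). The bounds overlapped, so the test did not decide, and single libraries moved it both ways. Without vehicle replicate 4 the median was -0.34, 2 members passed upward and only the bound against a loss was met. Without vehicle replicate 1 it was -0.79, 5 members passed downward and only the bound for a loss was met. Without 50 mg/kg replicate 1 or 3, 1 member passed downward. The bound against was changed for a time after its value was seen and then restored as first written.

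Hypoxia-list genes were lower at 50 mg/kg on both days. Scaling of the values to a fixed sum was argued against, since under 3 other scalings the median nearest to 0 on either day was -0.58. All 3 are relative, and the rescaling of protein-coding genes also sets a fixed sum, so they could not show a change of total RNA. Dilution of tumour cells by other cell types was argued against as well, because the lowest median of the luminal and basal lists on either day was -0.092, above the hypoxia list's upper quartiles of -0.25 and -0.65. Lower oxygen demand, better perfusion, smaller tumours or an effect on the transcription of these genes stay open and untested, as the labels record neither tumour size at collection nor oxygenation.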
